A study of Mus musculus with 16 samples.

How the data were processed

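Total RNA from cortical and hippocampal neurons of adult mice given tamoxifen or vehicle was measured by sequencing. The labels give 16 libraries in 4 groups of 4: cortical control, cortical tamoxifen, hippocampal control and hippocampal tamoxifen. RNA was extracted with Trizol and its quality read on a Bioanalyser, per the labels' protocols. Reads were aligned with STAR and counted with HTSeq on mm10, per the submitters' processing notes. Tool versions, the annotation release, the strand setting and how neurons were isolated are not given in the sources used here.

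The deposited count of each gene is a whole number of reads, not normalized, for 39179 genes per library. The deposited RPKM value beside it, per the file headers, equals that count divided by exon length and by the library's total including unassigned reads. Recomputing it matched 100% of the values, and RPKM entered no test. Reads the counter gave to no gene stayed out of library sizes and tests. The share aligned to several places was 27.53 to 35.43% of all counts in the 16 libraries, and the share outside annotated genes 3.64 to 7.93%. Counts in genes ranged from 33236178 to 57195203 per library. Of the gene identifiers, 96.2% are in GENCODE M21, 99.9% of these on the same chromosome. Coordinates are those of the files, in mm10.

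Libraries 1 and 2, and libraries 3 and 4, of every group were counted as 1 sample each. Differences within these 8 pairs at 20 to 200 counts were 2.55 to 2.87 times the Poisson variance, and 2.76 to 4.5 times at over 2000 counts. The 16 other pairs of the same groups gave 3.49 to 8.16 times and 9.38 to 129 times. The coefficient of variation beyond counting was 4.38 to 7.35% within the neighbouring pairs and 14.1 to 43.1% in the others. The neighbouring libraries thus differed by somewhat more than sampling noise, but far less than other libraries of their group, so their counts were added. This gave 8 samples, 2 per group, called sample A (libraries 1 and 2) and sample B (libraries 3 and 4), with 83527470 to 108293362 counts in genes. The labels do not say which libraries share an animal, and the grouping was decided from the values after the files were seen. The design written beforehand counted the 16 libraries separately. That fit is given as an alternative, and its p-values are too small if neighbouring libraries are repeats of 1 sample. With 2 samples per group, p-values measure only the spread between these samples.

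Genes were filtered with filterByExpr, leaving 18074, scaled with TMM and fitted with a mean per group over all 8 samples in edgeR 4.0.16 (R 4.3.3), using the robust quasi-likelihood test. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast with a threshold of 0.05. The contrasts were tamoxifen against control in each region, the difference of these 2 effects, and hippocampal against cortical controls. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. CPM, counts scaled to library size, use TMM library sizes. The 34 gene lists (18 programs and 16 cell type or region marker lists), the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry (limma 3.58.1). Of 725 list entries, 723 had a gene in the files and 705 were tested. Entries were matched by symbol, so the presynapse list of 30 entries gave 31 tested genes, each counted as a member below. Genes named were Tert and, in each direction, up to 10 genes past the threshold with the largest change, a mean of at least 1 CPM and no overlap between groups (5 for the difference between regions and for the region contrast, without the overlap condition). Where fewer than 5 qualified, those of smallest p filled up to 5 and are named as not passing. Predicted genes, Rik, mitochondrial, pseudogene and sex-linked entries were left out of these picks. Some genes the rule takes are not reported here. Exact permutation tests were two-sided.

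On data simulated for 2 against 2 samples with the observed spread, 27% of 100 genes changed 2-fold and 99% of 100 genes changed 8-fold were recovered among 17886 genes, with 6 false calls. Each simulated gene took the average spread of genes at its level, without scatter between genes. In the data, Gm11223 with a cortical log2 fold change of -4.06 had an edgeR adjusted p of 0.815. The recovered shares may thus be too high here, and 0 calls do not exclude large changes. The list test, run on 18074 genes, called the list that was moved and 0 of 33 others. Simulated genes varied independently and the other lists were random, so the low preset correlation held by construction. In the cortical contrast the estimated correlation ran from -0.038 (p53 targets) to 0.971 (endothelial cells). The simulation therefore cannot give the rate of false list calls in these data. Alternatives were RLE and upper quartile scaling, no count filter, a filter at 1 CPM, DESeq2 1.42.0, limma voom with quality weights, a test for folds over 1.2, the replicate number as a block, 1 surrogate variable (sva 3.50.0), only the samples compared, and leaving out each library. The merging was itself decided after seeing the data, so the 16 libraries counted separately, the design written beforehand, became an alternative. Added after seeing the data were that fit with the replicate block, limma voom with an estimated correlation between the libraries of a sample, and leaving out each sample. Counts of leave-outs below take libraries and samples together. Leaving out 1 library keeps the other, similar library of its sample in the fit. The contrast averaged over both regions, also added then, was refitted with the replicate number as a block, with same-numbered samples of both regions summed, in limma voom with and without a correlation between them, and without each sample. Sex was not fitted, since all 16 libraries had 3134 to 8731 Xist counts and 0 counts of Ddx3y, Eif2s3y, Kdm5d and Uty. Stretches shared between genes were counted in the GENCODE M21 transcripts. Figures were drawn with matplotlib 3.10.9.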

Results

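RNA was sequenced from cortical and hippocampal neurons of adult TERT-AD mice, in which tamoxifen is meant to switch on Tert, the catalytic subunit of telomerase. The 16 libraries formed 4 groups of 4, and neighbouring libraries were so alike that they were counted as 8 samples, 2 per group (A and B), a choice made from the values, while the design written beforehand had 16. Samples held 83527470 to 108293362 counts in genes. Transcripts of other cell types were abundant in these neuron samples: Mbp of myelin stood at 14400 to 56300 CPM, Gfap of astrocytes at 165 to 692 CPM and the microglial receptor Cx3cr1 at 127 to 372 CPM. The first principal component held 59% of the variance and the second 15%.

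**Figure D1:**
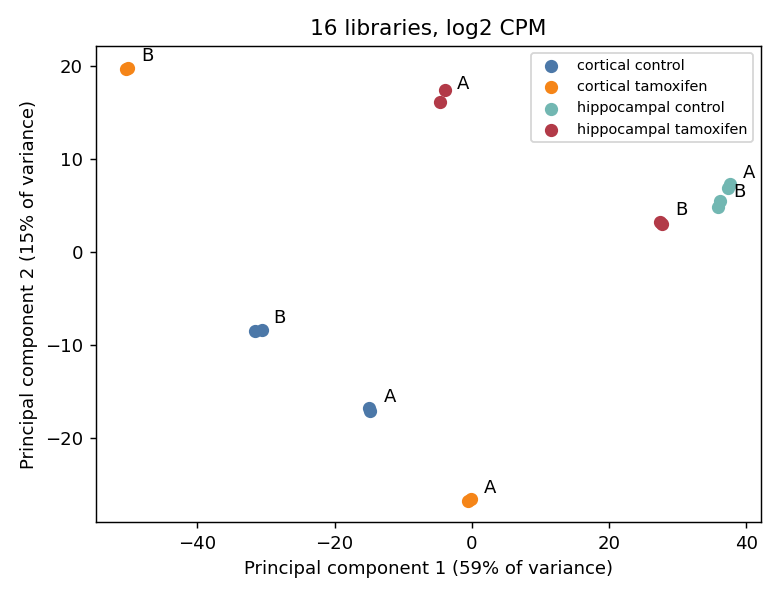
Principal components 1 and 2 of log2 CPM for the 16 libraries, coloured by group, with A and B marking the neighbouring libraries counted as 1 sample. Component 1 holds 59% and component 2 holds 15% of the variance, and samples A and B of the cortical tamoxifen group lie far apart. Those of the hippocampal tamoxifen group lie apart on component 1 too, with A at -3.96 and -4.68 and B at 27.35 and 27.63. That sample A is close to cortical tamoxifen sample A on component 1 (-0.59 and -0.18) but not on component 2.

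Tert was measured first, as the gene the treatment should raise. The sources used here do not say whether transcripts of the transgene are counted under Tert, so its level may not show whether the treatment worked. It was low in every sample, with 15 to 230 counts per library. In cortex the control samples stood at 0.546 and 1.32 CPM and those labelled tamoxifen at 1.26 and 2.05 CPM, a log2 fold change of 0.83 (SE 0.67, n = 2 per group, edgeR adjusted p = 0.834). In hippocampus the controls stood at 1.29 and 3.59 CPM and the samples labelled tamoxifen at 0.931 and 2.04 CPM, a log2 fold change of -0.72 (SE 0.65, edgeR adjusted p = 1). The difference of log2(CPM + 0.5) gave an exact permutation p of 0.667 in each region, and 2 against 2 samples cannot go below 0.333. With the libraries counted separately the exact permutation p was 0.143 in cortex and 0.314 in hippocampus. Sample B stood above sample A in all 4 groups, and between samples of the same letter Tert was higher with the tamoxifen label in both cortical pairs and lower in both hippocampal ones. With the pairs as a replicate block the exact permutation p was 0.5 in each region, the smallest that 2 pairs can give. The levels of the 2 groups thus overlapped in each region, and whether Tert differed within cortical pairs stays open, so groups are named by their label below. The cortical log2 fold change was 0.33 without control sample A, 1.6 without control sample B and 0.44 without sample B labelled tamoxifen, and the hippocampal one 0.2 without control sample B, -0.26 without sample A labelled tamoxifen, -1.27 without control sample A and -1.38 without sample B labelled tamoxifen.

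**Figure D2:**
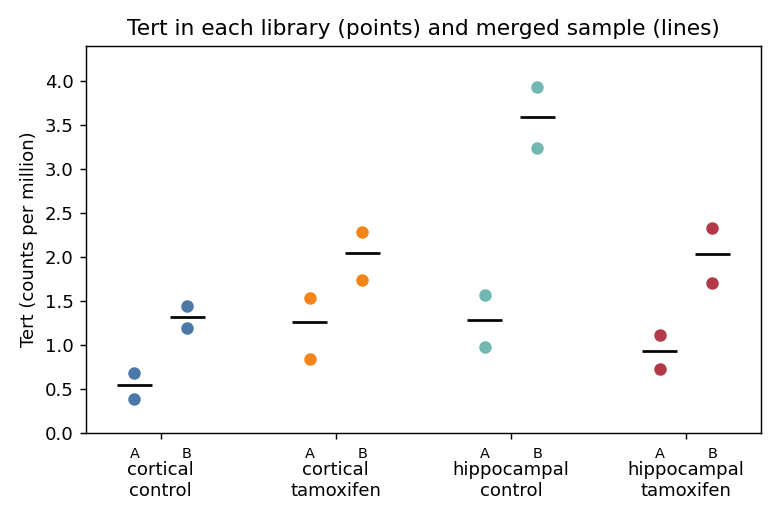
Tert in CPM (counts scaled to library size) for each library (points) and each merged sample (black lines), by group, with samples A and B side by side. The groups overlap in both regions, and the highest level, 3.59 CPM, is in hippocampal control sample B.

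In cortex, the genes of the astrocyte list stood lower in both samples labelled tamoxifen than in both controls. Of the 34 lists, 4 separated in this way downwards and 3 upwards, where chance would separate 33.3%, so separation alone does not set this list apart. All 11 measured members had a negative log2 fold change, among them the water channel Aqp4 (-0.62, SE 0.15), the growth factor receptor Fgfr3 (-0.58, SE 0.14), the gap junction gene Gja1 (-0.44, SE 0.13) and the glutamate transporter Slc1a3 (-0.47, SE 0.16). 5 of the 11 passed when adjusted over the list alone and 0 when adjusted over all genes. The list's mean was 7.90 and 7.62 log2 CPM in samples A and B, against 8.13 and 8.20 in the controls (camera adjusted p = 1.4e-08, and adjusted p = 0.812 with an estimated correlation). Among single genes, Fabp7, a lipid-binding protein of glia, stood at 12.5 and 11.1 CPM against 21.6 and 22.0 CPM in the controls, without passing the test (log2 fold change -0.88, SE 0.15, edgeR adjusted p = 0.83).

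0 of 18074 genes passed the edgeR test in cortex, 899 had an unadjusted p under 0.05, and the smallest adjusted p was 0.269. The genes of smallest p by the naming rule, none of which passed, had positive log2 fold changes for Thsd7b (2.03, SE 0.40), Matn2 (1.39, SE 0.34), Kit (0.93, SE 0.24, but 0.56 without sample B labelled tamoxifen) and Zdhhc23 (1.15, SE 0.30). They had negative values for Fabp7, Slc9a3r1 (-0.58, SE 0.12), Man1a2 (-0.77, SE 0.16), the hedgehog effector Gli2 (-0.98, SE 0.20) and the glutamate receptor subunit Grin2c (-0.66, SE 0.15). DESeq2 called 8 genes, among them Fabp7, Thsd7b and, with the smallest p, Msx3, Gm10036 and Gm11223 (described below). Limma voom with quality weights called 0, and edgeR on 16 separate libraries, the design written beforehand, 562 (208 higher, 354 lower). Allowing for correlated libraries, limma voom called 15, including the astrocyte list members Aqp4, Fgfr3 and Slc1a2.

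Of the 34 lists, 8 were called in cortex. The 3 called higher were the presynapse list (26 of 31 members with a positive sign, adjusted p = 0.000163), the excitatory neuron list (8 of 9, adjusted p = 0.000569) and the inhibitory neuron list (10 of 11, adjusted p = 0.0495). Examples were the vesicle protein Sv2b (1.39, SE 0.50) and the peptide Sst (0.99, SE 0.40), neither of which passed as a single gene. Sv2b stood at 43.5 CPM in sample A and 153 CPM in sample B labelled tamoxifen, against 35.2 and 39.8 CPM in the controls. Besides astrocytes, the lists called lower were cytosolic ribosomal proteins (70 of 76 members with a negative sign, adjusted p = 7.83e-05), mural cells (9 of 9, adjusted p = 0.000163), endothelial cells (10 of 10, adjusted p = 0.000163) and inflammatory cytokines (18 of 24, adjusted p = 0.000633). Each of the 8 had an adjusted p = 0.812 with an estimated correlation, and fry called 0 of 34. Sample B of the group labelled tamoxifen stood apart, with Slc17a7 at 952 CPM against 510 to 529 CPM in the other cortical samples, Mbp at 14400 CPM against at least 42400 CPM, and Cldn5 of endothelium at 69.3 CPM against at least 146 CPM. Its 2 libraries had 20.1 and 20.69% of counts in mitochondrial genes against 29.68 to 32.08% in the other cortical libraries, and 7.51 and 7.93% outside annotated genes against 5.48 to 6.53%. Without that sample the presynapse, excitatory neuron, inhibitory neuron, mural, endothelial and inflammatory lists had adjusted p values of 0.505, 0.906, 0.438, 0.378, 0.604 and 0.861, and the ribosomal list turned to a mean of 0.16 (adjusted p = 2.56e-07). Only the astrocyte list kept its call and sign, the inhibitory neuron list had an adjusted p = 0.27 without control sample A and lost its call in 7 of 12 leave-outs, and without sample A labelled tamoxifen 2038 genes were called.

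In hippocampus, the interferon response list stood higher in samples labelled tamoxifen, at 2.67 and 2.48 log2 CPM against 2.05 and 2.28 in the controls, with 21 of 24 members positive (camera adjusted p = 7.11e-06, and adjusted p = 0.659 with an estimated correlation). Its members of smallest p were Ifit3 (log2 fold change 1.16, SE 0.29) and the interferon regulator Irf7 (1.01, SE 0.35), neither past the test. The disease-associated microglia list stood lower, at 5.06 and 5.26 against 5.37 and 5.88, with 16 of 20 members negative (camera adjusted p = 7.11e-06, and adjusted p = 0.659 with an estimated correlation). Spp1 (-1.49, SE 0.52), Cst7 (-1.60, SE 0.64), Clec7a (-1.28, SE 0.50) and the protease Ctsd (-0.64, SE 0.22) were among them. General microglia markers had 13 of 13 negative signs, led by Cx3cr1 (-0.39, SE 0.22), with an adjusted p = 0.0126, and an adjusted p = 0.711 with an estimated correlation, but their levels of 7.07 and 6.81 overlapped the controls at 6.84 and 7.43. Control sample B carries much of both microglial results: without it the disease-associated list had a mean of -0.19 (adjusted p = 0.145) and the general list 0.1 (adjusted p = 0.266), and without sample B labelled tamoxifen the general list had -0.11 (adjusted p = 0.665). The interferon list was called in every leave-out. In cortex it had 20 of 24 members positive but was not called (camera adjusted p = 0.0756). Cortical samples labelled tamoxifen stood at 2.69 and 1.82 log2 CPM against 2.06 and 2.01 in the controls. A difference of its effect between the regions was not called (camera adjusted p = 0.202).

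Markers of inhibitory neurons were positive for 11 of 11 members in hippocampus, with Gad1 (0.50, SE 0.26), Gad2 (0.56, SE 0.28) and Pvalb (0.65, SE 0.28) as examples (camera adjusted p = 1.29e-05). The presynapse list had 30 of 31 members positive (adjusted p = 4.31e-05), the postsynapse list 32 of 35 (adjusted p = 0.000419), the astrocyte list 9 of 11 (adjusted p = 0.0017), the oligodendrocyte precursor list 8 of 8 (adjusted p = 0.00719) and the cortical region list 11 of 13 (adjusted p = 0.0472). Negative were choroid plexus (8 of 10, adjusted p = 0.0127), inflammatory cytokines (20 of 24, adjusted p = 0.0144), amyloid processing and Alzheimer risk (19 of 26, adjusted p = 0.0394), leukocytes (7 of 10, adjusted p = 0.0446) and the heat shock list (18 of 26, adjusted p = 0.0446). In the heat shock list, the endoplasmic reticulum genes Sdf2l1 (-0.76, SE 0.18) and Calr (-0.51, SE 0.16) went against the inducible chaperones Hspa1a (1.11, SE 0.38) and Hspa1b (1.32, SE 0.40). None of these genes passed the test, and a split within the list was not tested. With an estimated correlation the inflammatory list had an adjusted p = 0.693 and the others in this paragraph an adjusted p = 0.659. In all, 14 of 34 lists were called, 8 without control sample B and 5 without the sample A labelled tamoxifen, which stood apart with Ttr at 33.9 CPM against 6780 to 14000 CPM in the other hippocampal samples. Without that sample A the adjusted p values were 0.77 for the postsynapse list (6.74 and 6.44 log2 CPM in samples A and B against 6.38 and 6.42 in controls), 0.144 for astrocytes, 0.584 for oligodendrocyte precursors, 0.99 for the cortical region list, 0.99 for choroid plexus, 0.192 for inflammatory cytokines, 0.276 for amyloid processing, 0.385 for leukocytes and 0.963 for heat shock. Without control sample B they were 0.164 for oligodendrocyte precursors, 0.401 for the cortical region list, 0.957 for inflammatory cytokines, 0.164 for amyloid processing, 0.0535 for leukocytes and 0.172 for heat shock. Without control sample A they were 0.0933 for choroid plexus and 0.182 for leukocytes, and without sample B labelled tamoxifen 0.0587 for amyloid processing. Some of these calls also ended when 1 library was left out, so that amyloid processing lost its call in 7 of 12 leave-outs, leukocytes in 7, the cortical region list in 7 and heat shock in 8. The presynapse and inhibitory neuron lists were called in all 12. The postsynapse list had a mean log2 fold change of 0.2 in hippocampus and 0.19 in cortex. It was not called in cortex (camera adjusted p = 0.169) or for the difference between regions (camera adjusted p = 0.29).

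**Figure D3:**
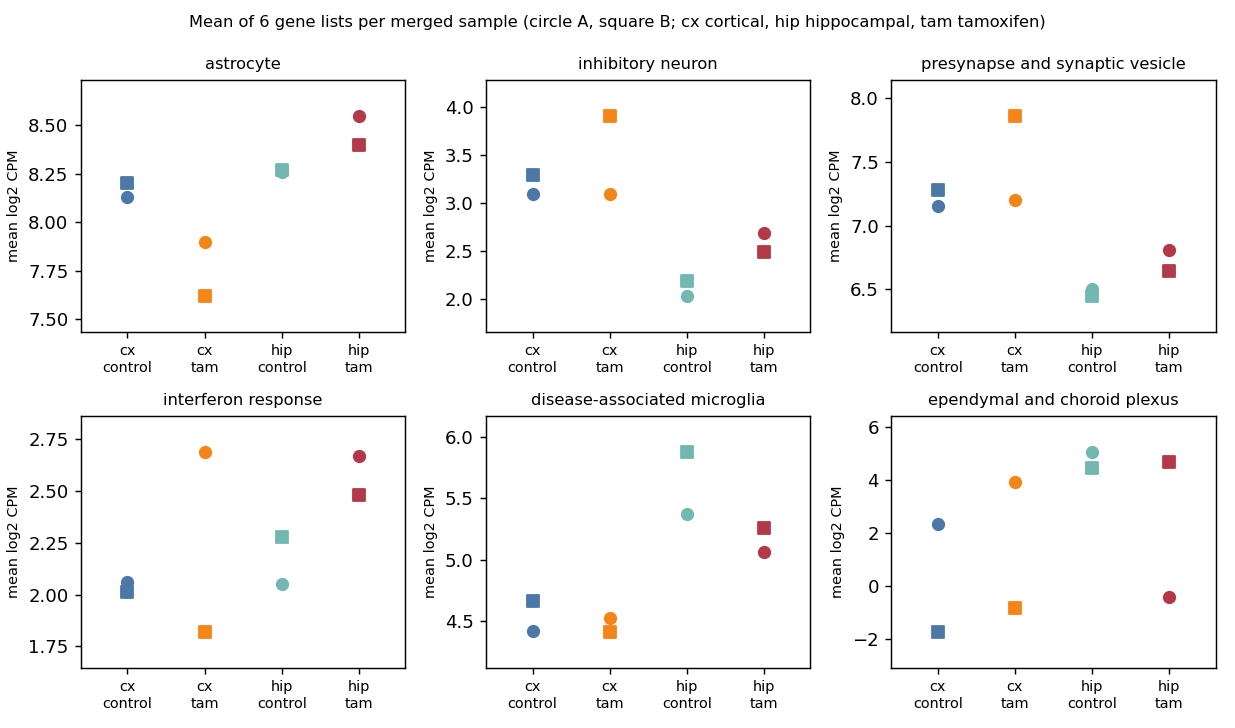
Mean log2 CPM of 6 gene lists in each merged sample, by group (circle sample A, square sample B). The astrocyte list lies below the controls in both cortical samples labelled tamoxifen (7.90 and 7.62 against 8.13 and 8.20) and above them in both hippocampal ones (8.55 and 8.40 against 8.26 and 8.27). By chance, 33.3% of lists would separate in this way, up or down, within a region. Of 34 lists, 3 lay above and 4 below the controls in cortex, and 9 above and 7 below in hippocampus.

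0 of 18074 genes passed the edgeR test in hippocampus, 653 had an unadjusted p under 0.05, and the smallest adjusted p was 0.333. The naming rule leaves out Msx3, Gm10036 and Gm11223, which had smaller p and are described below. The genes of smallest p by that rule had positive log2 fold changes for Proca1 (0.81, SE 0.16), the potassium channel Kcnj16 (0.61, SE 0.12), the clock gene Per3 (0.60, SE 0.12), the peptidase Ecel1 (1.88, SE 0.39) and Itih3 (0.67, SE 0.15). They had negative ones for Man1a2 (-0.88, SE 0.16), Sepn1 (-0.59, SE 0.13), Npnt (-0.73, SE 0.16), Sdf2l1 and Tmem64 (-0.46, SE 0.11). Each had an edgeR adjusted p = 1. Sepn1 lies on chromosome 4 at 134537892, within 5 Mb of Stmn1 and Rpl11, where 15.7% of other genes had an unadjusted p under 0.05 averaged over both regions against 3.47% elsewhere, none of them past the test. DESeq2 called 8 genes, among them Ecel1, Man1a2, Msx3, Gm10036 and Gm11223, limma voom with quality weights 0, limma voom with correlated libraries 3 (Itih3, Man1a2 and Etnppl) and edgeR on 16 separate libraries 318 (209 higher, 109 lower). Man1a2, a mannosidase that trims glycans, stood at 39.0 and 32.6 CPM in cortical and 28.8 and 29.0 CPM in hippocampal samples labelled tamoxifen, below the controls at 48.4 to 66.5 CPM.

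Msx3, Gm10036 and Gm11223 were singled out after their values were seen, since they had large differences in both regions. Msx3, a homeobox gene on chromosome 7 (140047300 to 140049140), stood at 1.10 to 1.82 CPM in the 4 control samples and 0 to 0.0348 CPM in the 4 labelled tamoxifen. Gm10036 on chromosome 18 (15832794 to 15833330) stood at 16.5 to 47.8 CPM against 0.718 to 1.13 CPM, and Gm11223 on chromosome 4 (69925201 to 69926171) at 22.9 to 81.8 CPM against 2.29 to 3.77 CPM. Their log2 fold changes were -7.64 (SE 0.77), -5.24 (SE 0.54) and -4.06 (SE 0.53) in cortex, with edgeR adjusted p of 0.269, 0.269 and 0.815. The Msx3 value rests on 1 and 0 counts in the cortical samples labelled tamoxifen, so its size is uncertain (-10.18 without sample A and -6.45 without sample B). In hippocampus they were -5.66 (SE 0.62), -5.00 (SE 0.54) and -3.94 (SE 0.53), with edgeR adjusted p of 0.333, 0.333 and 0.955. DESeq2 called all 3 genes in both regions, with adjusted p values in cortex of 0.000174 for Msx3, 6.67e-29 for Gm10036 and 2.28e-17 for Gm11223, and in hippocampus of 1.3e-11, 4.3e-26 and 6.11e-16. Without a count filter edgeR called Msx3 in cortex (adjusted p = 0.0282), and without cortical sample A labelled tamoxifen Msx3 and Gm10036 (0.00783 and 0.0378). Averaged over both regions, a contrast added after seeing the data, Msx3 and Gm10036 were the 2 genes that passed (edgeR adjusted p = 0.0304 for each), with Gm11223 at 0.0972. That fit takes the regions as independent. With the replicate block the adjusted p values were 0.111 for Msx3 and 0.0749 for Gm10036, with same-numbered samples of both regions summed 0.0723 and 0.239, and 0 genes passed in either. Leaving out 1 sample, Msx3 passed only without cortical sample A (0.0133) or B (0.0449) labelled tamoxifen and Gm10036 only without that sample A (0.0312). Gm10036 and Gm11223 share sequence with Rpl11 and Stmn1, so their counts are uncertain.

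The astrocyte list also led the comparison of the 2 regions' effects. Its difference, hippocampal minus cortical, had a mean of 0.60 on the log2 scale, with 10 of 11 members positive, among them Gja1 (0.80, SE 0.18), Gjb6 (0.70, SE 0.16) and Fgfr3 (0.79, SE 0.19). 7 members passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 3.52e-10, and adjusted p = 0.886 with an estimated correlation). The naming rule gave Gli3 (1.07, SE 0.17), Kcnj16 (0.95, SE 0.17), the cystine transporter Slc7a11 (0.91, SE 0.17), Slc13a5 (0.93, SE 0.18) and Bmpr1b (0.85, SE 0.18) as more positive in hippocampus. It gave Thsd7b (-2.82, SE 0.55), the matrix protein Matn2 (-2.29, SE 0.48), Otud1 (-0.80, SE 0.17), Gla (-1.25, SE 0.29) and Pdia6 (-0.90, SE 0.22) as more negative. None passed (edgeR adjusted p = 0.889 each). 0 of 18074 genes passed, 981 had an unadjusted p under 0.05, DESeq2 called 4 (Gli3, Matn2, Thsd7b and Kcnj16), limma voom with quality weights 0, limma voom with correlated libraries 112 and edgeR on 16 separate libraries 867. Over 18074 genes, which are not independent replicates, the 2 regions' log2 fold changes had a Pearson r of -0.088 and a Spearman rho of -0.021. On differences of mean log2 CPM, which the permutation used, Pearson r was -0.158 and Spearman rho -0.027. Permuting labels within regions gave two-sided permutation p values of 0.778 and 0.889 for these, over 36 labelings. Swapping the 2 labels within a region only turns the sign, so no p under 0.05 was possible.

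Control hippocampal and cortical samples differed in 1118 genes, 489 higher and 629 lower in hippocampus, but with same-numbered controls paired as a replicate block 0 genes were called, the genes named here included. The block adds terms to a fit of the same 8 samples and leaves less information on the spread, so this loss of calls does not show that the regions are alike. Hippocampal samples were higher in Fibcd1, a CA1 marker (log2 fold change 3.50, SE 0.24, edgeR adjusted p = 0.0103), the dentate gyrus gene C1ql2 (3.07, SE 0.26), Npy2r (3.02, SE 0.32), Fcgbp (3.46, SE 0.72) and Ccbe1 (3.10, SE 0.66). They were lower in the dopamine receptor Drd2 (-4.70, SE 0.57), Rspo1 (-4.02, SE 0.57), Kcnh4 (-3.96, SE 0.46) and Scn4b (-3.92, SE 0.54). Of the hippocampal region list 5 of 17 members rose and 0 fell, and of the cortical region list 8 of 13 fell, with Lamp5 (-2.76, SE 0.47) and Mef2c (-1.57, SE 0.30) among them. Of the striatal neuron list 3 of 7 fell, with Drd2 and Adora2a (-2.59, SE 0.53) among them. Drd2 stood at 10.3 and 7.82 CPM in cortical controls and 0.335 and 0.358 CPM in hippocampal ones.

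Glial genes differed between the control regions too. Of the disease-associated microglia list 9 of 20 members were higher in hippocampus and 0 lower, including Gpnmb (1.75, SE 0.23) and Ctsd (1.36, SE 0.22), and of the microglia list 6 of 13, including P2ry12 (1.2, SE 0.20). Of the presynapse list 7 of 31 were lower. In all 19 of 34 lists were called by camera. With an estimated correlation the smallest adjusted p was 0.239, for the hippocampal list, followed by 0.279 each for the cortical, leukocyte and meningeal fibroblast lists. Fry called 7 lists, among them the hippocampal (adjusted p = 0.00286), leukocyte (0.0149), meningeal fibroblast (0.0191) and cortical (0.039) lists. The leukocyte and meningeal fibroblast lists stood higher in hippocampus, with mean log2 fold changes of 1.57 and 1.66. Leaving out any 1 of the 4 control samples ended nearly all gene calls, with 0 to 2 genes left, and with the libraries counted separately 6982 genes were called.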

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

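The tests of stretches shared with other genes, of neighbours of Msx3, Gm10036 and Gm11223, and of further choroid plexus genes were fixed before their results were seen. The other tests here were chosen after.

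Msx3, Gm10036 and Gm11223 were low in all 4 samples labelled tamoxifen, for 3 of 3 genes below every control sample. Of the 50-base stretches in their transcripts, 66.8% of Gm10036 (nearly all in Rpl11) and 87.5% of Gm11223 (in Stmn1) occur in other genes, and 0% of Msx3, which argues against shared reads for Msx3. For the other 2 the overlap alone predicts no difference between labels. Averaged over both regions Rpl11 stood at -0.08 (SE 0.14) and Stmn1 at 0.20 (SE 0.11), against -5.12 and -4 for Gm10036 and Gm11223, which argues against a constant share of their reads. A share that differs between alleles stays open. Rpl11 and Stmn1 both lie on chromosome 4, at 136028265 and 134468320, and 15.7% of the 210 other tested genes within 5 Mb of them had an unadjusted p under 0.05 in the averaged contrast, against 3.47% elsewhere (Fisher's exact p = 9.53e-13, neighbours not being independent). Around the 3 genes themselves the share was 6.9%, under 2 times that of other genes (3.58%, Fisher's exact p = 0.0364), so a strain difference there stays open. For Gm10036 and Gm11223, a candidate explanation is that the animals of the 2 labels carry different strain alleles on chromosome 4. It would not by itself account for Msx3, which lies on chromosome 7 and shares 0% of its stretches. Treatment and such a difference between animals cannot be told apart, since each sample has 1 label.

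The astrocyte list differed between the regions' effects by the test of the difference (camera adjusted p = 3.52e-10), but not with an estimated correlation (adjusted p = 0.886). Sample B of the cortical group labelled tamoxifen does not carry the cortical part alone, since without it the mean was -0.26 and the list was still called. A different share of astrocyte RNA predicts that members move alike, and 0 of 11 members in cortex and 1 of 11 in hippocampus lay over 2 SE from the list's median, so a different mixture of cells may account for it. With 2 samples per group these SE are wide, and an effect of treatment on astrocytes was not tested apart from the mixture.

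The choroid plexus list differed between the regions' effects (camera adjusted p = 0.00285), but not with an estimated correlation (adjusted p = 0.886). Its mean difference of -3.1 ran from -7.51 to 1.54, turning positive without cortical tamoxifen sample A. The call was lost in 3 of 24 leave-outs, all of them of whole samples. Ttr varied between the samples of 1 group by up to 2040 times (cortical tamoxifen, 5690 and 2.79 CPM), which argues against treatment as its cause. All 7 of 7 choroid plexus genes outside the list, such as Otx2 and Aqp1, were highest in hippocampal control sample A, where Ttr reached 14000 CPM. Choroid plexus tissue in some samples is a likely source of these transcripts.

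Further lists whose effects differed between the regions by the test of the difference were cytosolic ribosomal proteins (camera adjusted p = 0.00688), endothelial cells (0.00896), oligodendrocyte precursors (0.0157) and heat shock genes (0.0259). None of these holds with an estimated correlation, where the adjusted p values were 0.999, 0.895, 0.895 and 0.886. Of 24 leave-outs the endothelial list lost its call or direction in 3, oligodendrocyte precursors in 4, heat shock in 5 and ribosomal proteins in 2. All these losses came from leaving out 1 of the 8 whole samples. The other leave-outs drop only 1 of the 2 alike libraries of a sample, so they test little. In 32 tests for a library far from the other 3 of its group, 2 were found. Hippocampal control library 1 had 49991243 counts in genes, and cortical control library 3 had 35.43% of counts aligned to several places. Chance flags about 1 in 20 when the 4 libraries are independent. Neighbouring libraries were alike, so the chance rate here is not known. In reads outside annotated genes, which entered no comparison, hippocampal samples labelled tamoxifen held 5.34 and 6.2% of counts, above the controls at 3.9 and 4.97%.

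For the counts of 0 genes in each region, 4 samples make 3 splits of 2 against 2, too few for a share under 0.05. The real split gave 0 genes and the highest of the other splits 0, in both regions, so 3 of 3 splits gave as many. With 0 genes in the real split no split can give fewer, so this comparison decides nothing.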

How the results depend on the processing

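Libraries counted separately are the design written beforehand, and merging them was chosen after seeing the data, as were the fits with correlated libraries and without whole samples. Scaling by RLE or upper quartile, a filter at 1 CPM and testing only the samples compared left 0 genes called for tamoxifen in both regions. Without a count filter 1 gene was called in cortex. DESeq2 called 8 genes in cortex, 8 in hippocampus, 4 for the difference between regions and 3207 between control regions. Libraries counted separately gave 562, 318, 867 and 6982, and correlated libraries in limma voom 15, 3, 112 and 3380, for the same comparisons. For control regions limma voom with quality weights gave 4743, the test for folds over 1.2 gave 281, 1 surrogate variable 23 and only the samples compared 4825. With the estimated correlation and with fry, 0 lists were called in cortex, 0 in hippocampus and 0 for the difference. The causes were not tested, except that folds over 1.2 is a stricter test and separate libraries double the libraries without adding samples and tested 16746 genes.

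The labels do not say whether a replicate number marks an animal. Deviations of same-numbered libraries correlated at 0.412 to 0.437 between the cortical groups, 0.212 to 0.262 between the control regions, -0.265 to -0.182 between the hippocampal groups and -0.5 to -0.486 between the tamoxifen regions, and 1 of 16 libraries correlated best with its own number. With 2 samples per group the 4 values of a comparison amount to 1, so pairing by number stays open for the cortical groups and the control regions. With the replicate block 0 genes were called in cortex, hippocampus and their difference, and 0 between control regions. The block adds terms to the fit, which leaves less information on the spread. Lists called were 8, 10 and 8, and the hippocampal lists not called were amyloid processing, heat shock, the cortical region list (adjusted p = 0.0516 each) and leukocytes (0.062). With libraries separate and the replicate block, 313 and 89 genes were called.

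Leaving out libraries or samples, where a lone sample is assumed to vary like the other groups, gave 0 to 2038 genes in cortex (2038 without cortical tamoxifen sample A, 1 without B) and 0 to 1106 between control regions. Lists called ranged from 7 to 14 in cortex, 5 to 14 in hippocampus and 3 to 11 for the difference. The correlation of effects ran from -0.288 to 0.221, turning positive in 3 cases: without cortical tamoxifen sample A (0.221), hippocampal control sample A (0.001) or hippocampal tamoxifen sample A (0.056). It has no p under the alternatives. In the averaged contrast the replicate block, summed regions and limma voom with and without correlated regions called 0 genes, and leaving out samples gave 0 to 939 (939 without cortical tamoxifen sample A). The hippocampal Tert log2 fold change ran from -1.38 to 0.2 without control sample B. Without cortical tamoxifen sample B the cortical means reached -0.02 for presynapse (highest 0.64), 0.03 for inflammatory cytokines (lowest -0.86), 0.16 for ribosomal proteins (lowest -0.49), 0.01 for excitatory neurons (highest 1.08), -0.11 for inhibitory neurons (highest 0.71) and 0.07 for endothelium (lowest -1.08), and for the difference between regions -0.16 for ribosomal proteins (highest 0.5) and -0.05 for endothelium (highest 1.1). Without hippocampal control sample B the hippocampal means were -0.05 for inflammatory cytokines (lowest -0.54) and 0.1 for microglia (lowest -0.49), and without hippocampal tamoxifen sample A -0.09 for choroid plexus (lowest -5.4). Tert had 15 to 230 counts per library, and whether depth limits its comparison was not tested. Samples of 1 group also differed, with hippocampal controls A and B at 1.29 and 3.59 CPM.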

Other observations

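The test by chromosome was chosen after the averaged contrast had been seen. Among genes with an unadjusted p under 0.05 in that contrast, chromosome 4 held 81 of 1177 tested genes (6.88%, Fisher's exact test adjusted p = 7.74e-07 over 30 chromosomes and unplaced sequences). These 81 include the 33 of 210 genes within 5 Mb of Rpl11 and Stmn1 counted above, and neighbouring genes are not independent. The count is thus not separate evidence. The next smallest adjusted p was 0.153, for chromosome 6. In controls, Gm10036 was 2.19 times as high in sample B as in sample A in cortex and 2 times in hippocampus, and Gm11223 2.1 and 2.44 times. Zfp511, next to Msx3 on chromosome 7, had an averaged log2 fold change of -0.63 (SE 0.13), and the Rpl11 and Stmn1 values were -0.08 (SE 0.14) and 0.20 (SE 0.11).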
